A study of Mus musculus with 9 samples.

How the data were processed

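Circular RNAs (circRNAs, closed loops made by back-splicing) were profiled in intestinal tumours of mice on 9 one-colour arrays, 3 in each of 3 groups named by the sample titles as CTR, HFD and HFD+Abx. HFD stands for a high-fat diet in the series' design text. Abx is not spelled out in the labels and is kept as written. Per the labels' protocols, total RNA was treated with RNase R, an exonuclease that digests linear RNA, and the remaining RNA was amplified with random primers and labelled with Cy3. The labels do not say whether the 3 arrays of a group came from separate animals, so the p-values measure the spread between these samples, part of which may be technical.

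The authors deposited a scanner table for each array with spot intensity values from Agilent Feature Extraction 11.0.1.1, per the file headers. The processed signal used here is the scanner software's background-corrected intensity, per the file headers, and it was not yet normalised between arrays. The authors also deposited a table of log2 values for 14218 circRNA probes. How that table was made is not given in the sources used here, although the submitters' processing notes name limma. Set against the scanner values, its columns followed the log2 median signal without background subtraction, with r from 0.998 to 1.00 across probes, and their medians lay between 5.80 and 5.82. The log2 scale was thus read from the values, and the method of normalisation stays unknown. This table was used only as an alternative.

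Each array carried 15712 spots, of which 15176 were not control spots. These held 14236 circRNA probes with 1 spot each and 94 other probes with 10 spots each, of which 50 were mRNA probes. Spots marked as outliers by the scanner software were left out (3 to 22 circRNA spots per array), and no spot was saturated. Values were log2 processed signals minus the array's 75th percentile over circRNA probes, and spots of one probe were averaged. The 13556 circRNA probes well above background on at least 3 of the 9 arrays were tested.

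Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the 3 group means in one model over all 9 arrays and no covariate. An adjusted p under 0.05 (Benjamini-Hochberg) was a call. The count at an unadjusted p under 0.05 with at least 1.5-fold is given beside it. A moderated F test asked whether any group differed. Where fewer than 6 circRNAs passed in a comparison, the rule was to take the 8 with the largest rise and the 8 with the largest fall in mean among those at an unadjusted p under 0.01 with groups that did not overlap. For opposite changes the rule was to take the 10 with the largest smaller change of the 2 among those at an unadjusted p under 0.05 in both comparisons, whether or not groups overlapped. The model, these rules and most alternatives were fixed before the data were examined. A probe that was not well above background on any array of a group has only a bound there. The fold is then given as at least the mean of the brighter group over the mean, per array, of the higher of the lowest signal well above background and the probe's own.

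The files name circRNA probes by an array ID and do not pair these IDs with host genes, circRNA names or positions. At most 2 IDs per direction are therefore printed. The planned tests of host gene lists and cell type markers could not be run, and neither the mouse counterpart of the circRNA in the series title nor circRNAs of Bcat2 were analysed here. The 50 mRNA probes carry transcript accessions, and 44 matched a gene symbol in a RefSeq table of GRCm38.p6, which was used for names only. Fitting these 50 probes by themselves was decided after seeing the data, and so were the genes named among them.

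Slides were read from the scan identifiers in the file headers, with arrays of the same identifier taken to share a slide. This places CTR 1 to 3, HFD 1 to 3 and HFD+Abx 1 on slide 1 and HFD+Abx 2 and 3 on slide 2. HFD and CTR were thus compared within one slide, whereas slide and HFD+Abx partly overlap. Results are given with slide as a block and on slide 1 alone where these change them. Since slide 2 holds HFD+Abx arrays only, the differences of HFD+Abx in both settings are those of HFD+Abx 1 alone, assumed to vary like the other groups. Within slides, CTR 1 to 3 and HFD 1 lie in position column 1 and all other arrays in column 2. CTR and HFD+Abx thus share no column, and a difference between them cannot be told apart from a column difference without the HFD arrays. With position column as a block, HFD vs CTR rests on HFD 1 alone, HFD+Abx vs HFD on HFD 2 and 3, and HFD+Abx vs CTR on both of these.

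Precision is limited by the number of arrays. In simulated data with 13494 circRNAs and the observed spread, in which 200 circRNAs were changed, the same code recovered 54.5% of 2-fold and 98.5% of 4-fold changes for HFD vs CTR, 57.5% and 99.0% for HFD+Abx vs HFD, and 56.0% and 99.5% for HFD+Abx vs CTR. That simulation gave every array independent noise, whereas real arrays can share deviations.

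Alternatives covered normalisation (quantile, percentile over probes detected on all arrays, equal medians), background correction (normexp with offset 50, run on the median signal because the files hold no mean signal), the authors' log2 table, filters on dim probes, variance models, array weights, blocks, samples left out and thresholds. Array position as a block, slide 1 alone, separate HFD arrays for the 2 comparisons, a filter against the negative probes, keeping outlier spots, all alternatives for the 44 other probes (fitting each kind alone among them) and adjusting the mRNA probes together with the circRNA probes were added after seeing the data.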

Results

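CircRNA levels were measured in mouse intestinal tumours of 3 groups, CTR, HFD (high-fat diet) and HFD+Abx, with 3 arrays each. Between 12544 and 13478 of the 14236 circRNA probes were well above background on an array, with the lowest number on HFD+Abx 3. Of the 15 probes named as negative, 8 were also well above background on all 9 arrays, so this mark does not show a specific signal. The median spot signal was 3.88 to 4.60 times its local background. All levels below are log2 signals relative to the 75th percentile of the same array, and differences are in log2 units.

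The arrays were first compared with each other. Mean correlations across circRNAs were 0.982 within CTR, 0.982 within HFD, 0.973 within HFD+Abx and 0.982 between CTR and HFD arrays. HFD 1 correlated most closely with CTR 3 (r = 0.991), CTR 2 with HFD 3 (r = 0.984) and HFD+Abx 1 with HFD 3 (r = 0.988), so nearest neighbours often lay in another group. The first principal component held 30.5% of the variance and set HFD+Abx 2 and 3, the arrays of slide 2, apart from the other 7. On the second, with 25.3%, these arrays lay far from each other, at -15.6 and 32.4. HFD+Abx 2 correlated less with HFD+Abx 3 (r = 0.974) than with HFD+Abx 1 (r = 0.981), CTR 2 (r = 0.979) and HFD 3 (r = 0.978). HFD+Abx 3 correlated most closely with HFD 2 (r = 0.975). Separation of the 3 groups over all circRNAs was as large or larger in 35 of the 280 possible groupings of the arrays (exact permutation p = 0.125). Between pairs of groups the exact permutation p was 0.60 for HFD and CTR, 0.30 for HFD+Abx and HFD and 0.10 for HFD+Abx and CTR, where 0.10 is the smallest that 3 arrays against 3 can give.

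**Figure D1:**
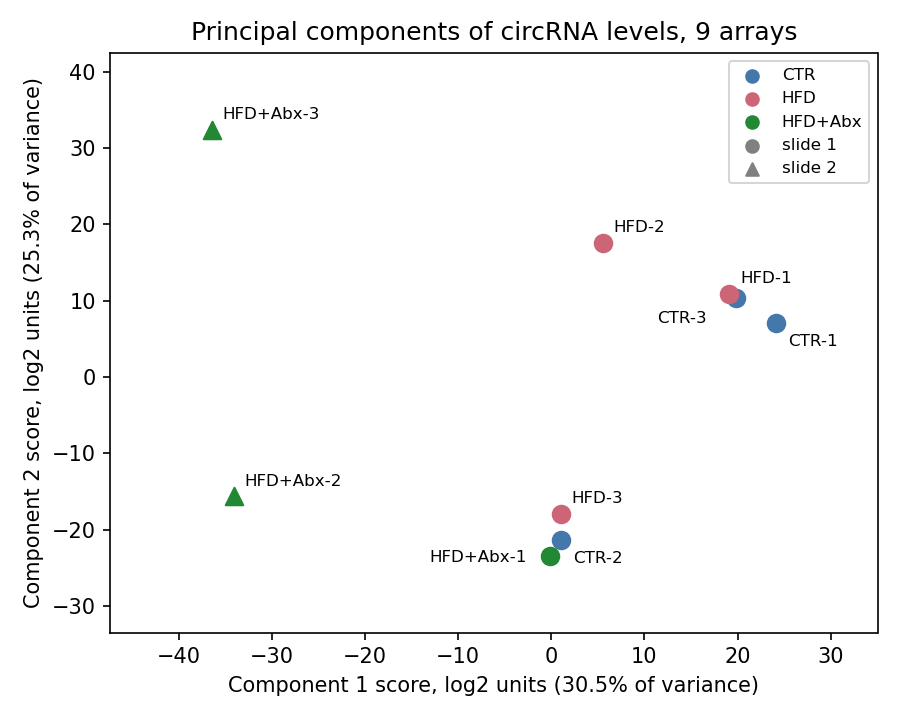
Scores of the 9 arrays on the first (x axis, 30.5% of variance) and second (y axis, 25.3%) principal components of circRNA levels in log2 units, with colours for groups and shapes for slides. The HFD+Abx arrays of slide 2 lie at -34.1 and -36.4 on the first component, and the HFD+Abx array of slide 1 lies at -0.16, next to CTR 2 and HFD 3.

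The first comparison asked which circRNAs differ in tumours under a high-fat diet. No circRNA passed the adjusted threshold in HFD vs CTR with limma (0 of 13555, smallest adjusted p = 0.91). At an unadjusted p under 0.05 there were 498, fewer than the 678 by chance if arrays varied independently. Of the 498, 244 differed by at least 1.5-fold, 209 higher and 35 lower in HFD. The largest rise among circRNAs taken by the naming rule was ASCRP4010398, with a mean of 2.33 ± 0.73 in HFD and 0.98 ± 0.27 in CTR (SD, n = 3). Its difference of 1.35 (SE 0.31, 95% interval 0.65 to 2.04) did not pass the adjusted threshold (adjusted p = 0.999). It was 0.51 (SE 0.26) with array position as a block, which compares HFD 1 alone with CTR. The largest fall in fitted mean under that rule was in ASCRP4002650, which was well above background on all 3 CTR arrays and on 0 of the 3 HFD arrays. With HFD at background, it was at least 1.18-fold lower in HFD, a bound that does not rank it among circRNAs measured in both groups. It did not pass the adjusted threshold (adjusted p = 0.999), and its fitted difference of -1.42 went to 0.018 with normexp background correction. Of the 8 circRNAs taken as higher, 7 differed by 1.12 to 1.35 and 1 was at background on all CTR arrays and at least 1.31-fold higher. Of the 8 taken as lower, 2 differed by -1.002 to -0.836 and 6 were at background on all HFD arrays and at least 1.02-fold to 1.44-fold lower. Counting single arrays too, 3 of the 8 higher and 7 of the 8 lower were not well above background on every array of both groups. None of the circRNAs taken either way passed. The groups did not overlap for 9.27% of circRNAs, where 10% is the share by chance. For 11960 circRNAs (88.2%) the 95% interval of the difference in probe signal, not adjusted for the number of probes, excluded a 2-fold change either way. That share was 83.8% for HFD+Abx vs HFD and 82.2% for HFD+Abx vs CTR. Only 3242 circRNAs were brighter than every negative probe on at least 3 arrays. For the others a narrow interval may reflect unspecific signal and does not exclude a 2-fold change of the circRNA. Leaving out CTR 3, HFD 1 or HFD 2 moved the 244 to 514, 439 and 140. Without CTR 2 the split was 165 higher and 153 lower, against 209 and 35 with it. The excess of higher over lower circRNAs thus depends on that array, mainly because more were lower without it. With array position as a block the count was 149 (110 higher and 39 lower).

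The second comparison asked what differs when Abx is added to the high-fat diet. No circRNA passed in HFD+Abx vs HFD with limma (0 of 13556, smallest adjusted p = 0.50). At an unadjusted p under 0.05 there were 1279, against 678 by chance if arrays varied independently. Of the 1279, 609 differed by at least 1.5-fold, 156 higher and 453 lower in HFD+Abx. With quantile normalisation that split was 242 higher and 263 lower, with normexp background correction 36 and 27, and among circRNAs brighter than every negative probe 49 and 44, so the direction of the majority depends on the processing. Without HFD+Abx 3 the split was 286 higher and 350 lower, and without HFD+Abx 2 it was 89 and 298. Of the 8 circRNAs taken as higher by the naming rule, 4 differed by 0.92 to 1.18 and 4 were at background on all HFD arrays and at least 1.31-fold to 1.77-fold higher. Of the 8 taken as lower, 6 differed by -1.90 to -1.36 and 2 were at background on all HFD+Abx arrays and at least 1.28-fold to 2.49-fold lower. Counting single arrays too, 7 of these 8 were not well above background on every array of both groups. The circRNA at -1.90 was well above background on only 1 HFD+Abx array, so the size of its fall is uncertain. All circRNAs taken either way had an adjusted p of 0.50 in limma, so none passed. The groups did not overlap for 12.8% of circRNAs, where 10% is the share by chance. With slide as a block 0 circRNAs passed and 308 met the unadjusted criterion, 207 higher and 101 lower. These are differences of HFD+Abx 1 alone, in which most were higher, whereas 453 of the 609 over the 3 HFD+Abx arrays were lower. On slide 1 alone, again with HFD+Abx 1 as the only HFD+Abx array, 1 circRNA passed, higher in HFD+Abx, and 347 met the unadjusted criterion (227 higher and 120 lower). Without HFD+Abx 1, when HFD+Abx and HFD share no slide, 2 circRNAs passed, both lower, and 1384 met the unadjusted criterion, and without HFD+Abx 2 it was met by 387.

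The third comparison set HFD+Abx against CTR. No circRNA passed with limma (0 of 13555, smallest adjusted p = 0.37). At an unadjusted p under 0.05 there were 1691, against 678 by chance if arrays varied independently. Of the 1691, 843 differed by at least 1.5-fold, 216 higher and 627 lower in HFD+Abx. That split was 308 and 452 with quantile normalisation. Without HFD+Abx 3, the array with the fewest probes above background, it was 329 higher and 465 lower, and without HFD+Abx 2 it was 125 and 375. The size of the excess of lower circRNAs thus depends on HFD+Abx 3. ASCRP4005906 had the largest rise under the naming rule, with 2.29 ± 0.72 in HFD+Abx and 0.85 ± 0.23 in CTR (SD, n = 3), a difference of 1.44 (SE 0.33, 95% interval 0.71 to 2.18). ASCRP4013451 had the largest fall, with 4.06 ± 1.16 in HFD+Abx and 6.62 ± 0.94 in CTR, a difference of -2.56 (SE 0.66, 95% interval -4.03 to -1.10). Neither passed the adjusted threshold (adjusted p = 0.37 for both). With replicate number as a block 2 circRNAs passed, both lower, among them ASCRP4013451 (adjusted p = 0.014 in limma). Same-numbered arrays did not all deviate together, so that block may not reflect a pairing of the arrays. For both circRNAs HFD+Abx 1 lay nearer to CTR than HFD+Abx 2 and 3 did. With slide as a block, which leaves HFD+Abx 1 alone to set against CTR, their differences were 0.61 and -1.28. With array position as a block they were 0.92 (SE 0.59) and -0.85 (SE 1.05). Without HFD+Abx 1 that of ASCRP4005906 was 1.85 and passed the adjusted threshold. The groups did not overlap for 15.2% of circRNAs, where 10% is the share by chance. With slide as a block 4 circRNAs passed, all higher in HFD+Abx, and 259 met the unadjusted criterion. Of these differences of HFD+Abx 1 alone, 208 were higher and 51 lower, the reverse of the majority over the 3 HFD+Abx arrays. On slide 1 alone 1 passed and 282 met it (218 higher and 64 lower). With array position as a block 0 passed and 243 met it (99 higher and 144 lower). Without HFD+Abx 1, when HFD+Abx and CTR share no slide, 32 circRNAs passed (2 higher and 30 lower) and 1782 met the unadjusted criterion, whereas without CTR 1 or HFD+Abx 2 it was met by 550 and 500.

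**Figure D2:**
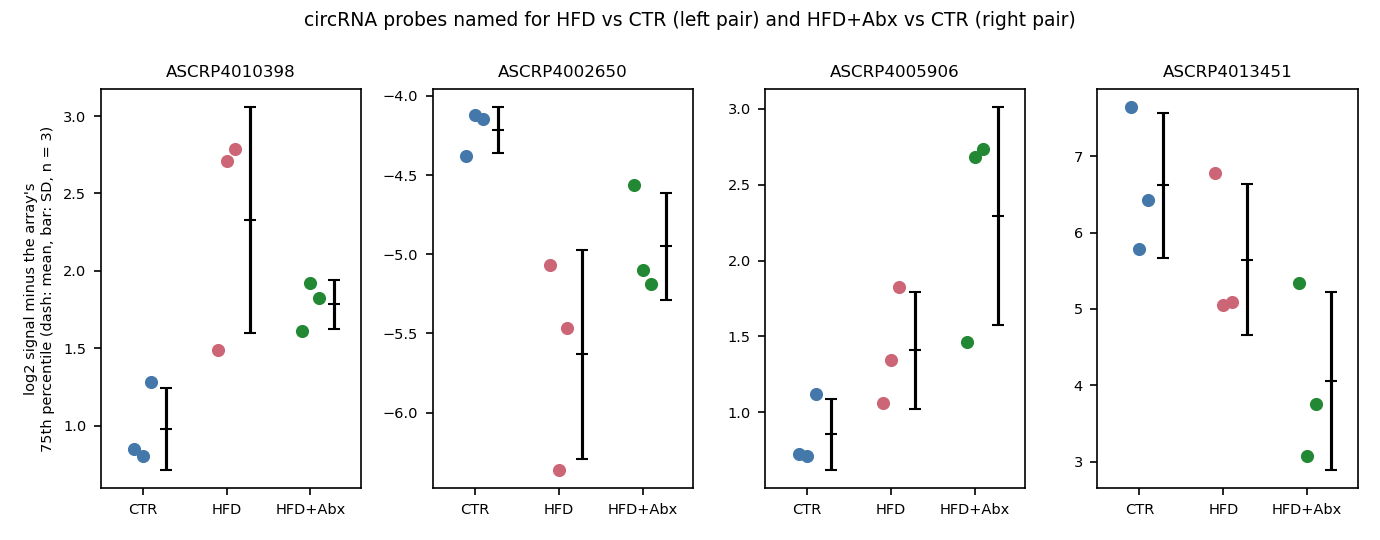
Levels of 4 circRNA probes on each array (points; y axis in log2 units relative to the array's 75th percentile), with the mean and SD of each group of 3. ASCRP4010398 and ASCRP4002650 were taken for HFD vs CTR and ASCRP4005906 and ASCRP4013451 for HFD+Abx vs CTR, and none of the 4 passed the adjusted threshold.

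The F test over the 3 groups called 0 of 13555 circRNAs in limma (smallest adjusted p = 0.56). At an unadjusted p under 0.05 it gave 1205, against 678 by chance if arrays varied independently. With replicate number as a block it called 1 circRNA. It called 1 circRNA without HFD+Abx 1 and 1 on slide 1 alone, and 0 with slide as a block.

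The groups also imply the question whether circRNAs that differ with HFD go back in HFD+Abx. No circRNA passed the adjusted threshold in both comparisons with opposite signs in limma. At an unadjusted p under 0.05 in both, 133 had opposite signs (118 higher and then lower, 15 lower and then higher) and 3 had the same sign. Because both comparisons use the HFD arrays, simulated groups without any change gave 154.2 opposite and 2.05 same on average, and independent lists would give 25.3 and 2.80 opposite in these directions. The simulated arrays had independent noise with the same spread in the 3 groups, whereas real arrays can share deviations. The 10 circRNAs taken by the rule for opposite changes went 5 in each direction, and none passed the adjusted threshold. Of these, 4 were at background on all arrays of at least 1 group, and the other 6 had smaller changes of 0.84 to 1.12 in size. Across circRNAs, which are not independent replicates, the 2 sets of changes correlated at r = -0.20, against -0.50 in the simulation. Their covariance was -0.016, against -0.029 in the simulation. Simulated r spanned only -0.52 to -0.47, whereas 100 regroupings of the real arrays, the real one included, spanned -0.78 to 0.038. With separate HFD arrays for the 2 comparisons, 1 for one and 2 for the other, r was below 0 in 1 of the 6 divisions and ranged from -0.12 to 0.28. Without CTR 2 the correlation was 0.0021, and among the 3242 circRNAs brighter than every negative probe it was 0.064. The 133 became 340 with normexp background correction, 10 among circRNAs brighter than every negative probe, 21 with array position as a block, 51 with slide as a block, 73 on slide 1 alone, and 72, 69, 208, 70 and 76 without CTR 1, CTR 2, HFD 1, HFD 2 and HFD+Abx 2.

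The arrays also carry 50 mRNA probes, 44 of them above background on all 9 arrays although linear RNA had been digested. Such signal need not be specific, since 8 of the 15 negative probes were also well above background on all 9 arrays. Only 3242 of the 13556 tested circRNAs were brighter than every negative probe on at least 3 arrays. The mRNA probes were not put through that filter. Gabrg1, which encodes a subunit of the GABA-A receptor, averaged -3.02 ± 0.07 in HFD+Abx, -2.76 ± 0.20 in HFD and -2.14 ± 0.51 in CTR (SD, n = 3). Between HFD+Abx and CTR it differed by -0.88 (SE 0.22). Uhrf1bp1l differed by -0.71 (SE 0.20) and Dnajc11, which encodes a mitochondrial protein, by -0.64 (SE 0.18). These 3 passed over the 50 probes alone in limma (adjusted p = 0.046 each, n = 3 per group), a family chosen after the data were seen, with each of the 3 HFD+Abx arrays below each CTR array. No mRNA probe passed when adjusted together with the circRNA probes, or with equal medians, where the differences were -0.87, -0.69 and -0.62. None passed with replicate number as a block. No probe passed with slide as a block, on slide 1 alone or with quantile normalisation, or when CTR 2, HFD 1, HFD 2, HFD+Abx 2 or HFD+Abx 3 was left out. The differences of the 3 probes were then -0.90, -0.75 and -0.66 without CTR 2, the same as over all arrays without HFD 1 or HFD 2, -0.92, -0.80 and -0.67 without HFD+Abx 2, and -0.89, -0.65 and -0.53 without HFD+Abx 3. With slide as a block, in HFD+Abx 1 alone, Gabrg1 differed by -0.96 (SE 0.33), Uhrf1bp1l by -0.77 (SE 0.28) and Dnajc11 by -0.47 (SE 0.24). With array position as a block they differed by -0.54 (SE 0.41), -0.27 (SE 0.36) and -0.47 (SE 0.34), and 0 passed. With quantile normalisation the 3 differed by -0.81 (SE 0.25), -0.69 (SE 0.19) and -0.53 (SE 0.14). With normexp background correction and an offset of 50, which shrinks differences between dim values, Gabrg1 differed by -0.24, Uhrf1bp1l by -0.31 and Dnajc11 by -0.14, and 0 passed. None of the 3 passed without CTR 1, where 1 other probe did. Only Gabrg1 passed without CTR 3. Without HFD+Abx 1, 4 probes passed, of these 3 only Dnajc11. With 1 array left out at a time, Gabrg1 differed by -1.13 to -0.62, Uhrf1bp1l by -0.80 to -0.65 and Dnajc11 by -0.72 to -0.53. In HFD+Abx vs HFD no mRNA probe passed in limma (3 at an unadjusted p under 0.05). Dnajc11 differed there by -0.70 (SE 0.18, adjusted p = 0.064). Ppara, a nuclear receptor that drives fatty acid oxidation genes, differed by -0.997 (SE 0.28, adjusted p = 0.064), and was well above background on 3 HFD arrays and 1 HFD+Abx array. Ppara and Dnajc11 were singled out after their values were seen. Both passed without CTR 1, without CTR 3 or without HFD+Abx 1 (2 probes each), Dnajc11 passed without HFD 3 (1 probe), and 1 probe passed without HFD 2. With slide as a block, in HFD+Abx 1 alone, Ppara differed by -0.50 (SE 0.38) and Dnajc11 by -0.53 (SE 0.24), and with normexp by -0.21 and -0.22. In neither case did a probe pass. In HFD vs CTR no mRNA probe passed in limma (2 at an unadjusted p under 0.05). Gabrg1 was already lower there, by -0.62 (SE 0.22, adjusted p = 0.33 in limma), and differed by -0.26 (SE 0.22) in HFD+Abx vs HFD. In HFD vs CTR Uhrf1bp1l differed by -0.35 (SE 0.20) and Dnajc11 by 0.06 (SE 0.18). On every array Gabrg1, Dnajc11 and Ppara lay below the median of the tested circRNAs, which was -1.49 to -1.33. Uhrf1bp1l lay below it on each HFD+Abx array and above it on each CTR array. The levels and differences of these 4 probes may thus reflect unspecific signal rather than the transcripts.

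**Figure D3:**
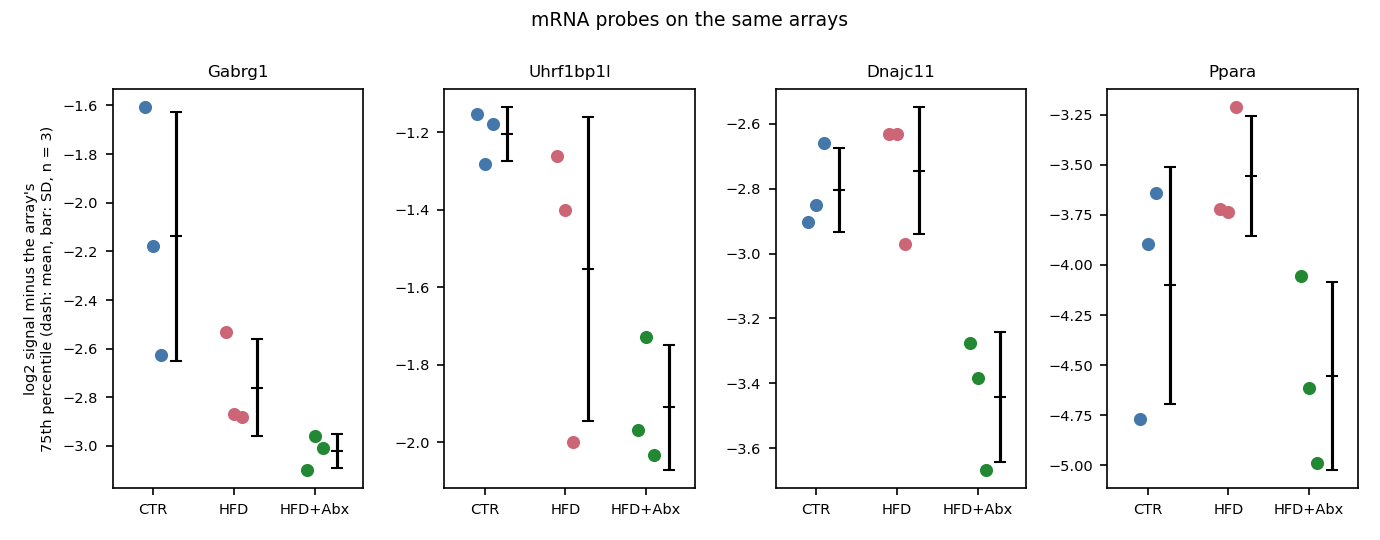
Levels of 4 mRNA probes on each array (points; y axis in log2 units relative to the array's 75th percentile of circRNA probes), with the mean and SD of each group of 3. Gabrg1, Uhrf1bp1l and Dnajc11 lay lower on each HFD+Abx array than on each CTR array, and Ppara averaged -3.56 in HFD and -4.55 in HFD+Abx without passing the test. The probes were not tested against the negative probes, so their signal may be unspecific.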

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

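With the 44 probes that are neither circRNA nor mRNA probes adjusted together, no result met the criteria for a closer look. Groups of 3 are too small for a test of single outlying arrays. Among these 44 probes none differed from CTR past the adjusted threshold of limma (smallest adjusted p = 0.12). This depends on adjusting 3 kinds of probe together. With each kind fitted alone, a choice made after the data were seen, 1 custom probe passed in HFD vs CTR (log2 difference 0.85, SE 0.20, adjusted p = 0.036), and 4 probes passed in HFD+Abx vs CTR, 2 of them custom probes and 2 of them probes named as negative. The 15 negative probes differed there by -0.95 to 0.42. The lowest of them passed (SE 0.27, adjusted p = 0.010 in limma) and was well above background on 1 array. A fall as large as that of Gabrg1 (-0.88) thus also arose in a probe named as negative. Adjusted together, 3 of the 44 passed in HFD+Abx vs CTR with array weights, 2 without CTR 2 and 3 without HFD+Abx 1. The tests of slides, the HFD+Abx condition, array position, linear RNA and exchanged labels below were chosen after the values they rest on had been seen.

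HFD+Abx 2 and 3 stood apart from the other arrays on the first principal component, but not as a close pair by correlation. Noise of dim probes was examined in HFD+Abx vs CTR. There 13.0% of the brightest 25% of circRNAs were at an unadjusted p under 0.05 in limma, against 14.3% of the dimmest 25%. Small p-values in that comparison were thus not confined to dim probes. The comparison includes HFD+Abx 1, so these shares cannot decide why arrays 2 and 3 stood apart. A slide difference and the HFD+Abx condition cannot be told apart, because only 1 HFD+Abx array shares a slide with the other groups and slide 2 holds no CTR or HFD array. The covariance of HFD+Abx 1 with arrays 2 and 3 was 0.23 of that between 2 and 3, and -0.83 to 0.55 over choices of reference arrays. Of the 2833 circRNAs that arrays 2 and 3 set apart from CTR at an unadjusted p under 0.05, 52.5% had the same sign in HFD+Abx 1 against HFD (48.5% to 56.7% with 1 HFD array left out). The share by chance is 50% only if higher and lower are balanced in either comparison, and it was not computed. Arrays 2 and 3 against CTR were not balanced, with 507 higher and 1275 lower at 1.5-fold or more.

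CTR and HFD arrays were interleaved. Arrays in the same position column of slide 1 correlated by 0.00238 more than those across columns (exact permutation p = 0.14 over 35 regroupings). The leading axis of the 6 arrays followed the mean of the mRNA probes at Pearson r = 0.56 (exact permutation p = 0.25) and Spearman rho = 0.49 (exact permutation p = 0.36), and at r = 0.17 without the 2 farthest arrays. With the labels of CTR 2 and HFD 1 exchanged, 912 circRNAs were at an unadjusted p under 0.05 in HFD vs CTR (real 489, highest of the other splits 1166) and 0 passed, whereas the F test over the 3 groups then called 78. Position, residual linear RNA and exchanged labels all stay open, and no biological explanation was tested.

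Changes with HFD and with HFD+Abx were opposed over all circRNAs tested, but not among those brighter than every negative probe (r = 0.064) or without CTR 2 (r = 0.0021). Because both comparisons use the HFD arrays, such opposition arises without a reversal: in 95 of 100 regroupings of the 9 arrays, the real one included, the correlation was as far below 0 as in the real groups (-0.21 on circRNAs with values on all arrays). With separate HFD arrays for the 2 comparisons, chosen after the result was seen, r was below 0 in 1 of 6 divisions (-0.12 to 0.28). A reversal in some circRNAs stays open.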

How the results depend on the processing

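No circRNA and no mRNA probe was called in HFD vs CTR, and no circRNA for opposite changes, under any of the alternatives run. HFD+Abx vs CTR gave 4 circRNAs with slide as a block and 1 on slide 1 alone, HFD+Abx vs HFD gave 1 on slide 1 alone, and the F test gave 1 there. With 1 array left out at a time the counts were 0 for HFD vs CTR and ranged from 0 to 2 for HFD+Abx vs HFD, 0 to 32 for HFD+Abx vs CTR and 0 to 1 for the F test. The replicate block gave 2 circRNAs for HFD+Abx vs CTR, 1 for the F test and 0 mRNA probes, and 1 of the 44 other probes in HFD vs CTR and 1 in HFD+Abx vs CTR. With group means taken out, same-numbered arrays did not all deviate together, with r from -0.37 to 0.39 (0.39 and 0.19 for numbers 2 and 3 of HFD+Abx and CTR). In these deviations, 3 of 9 arrays correlated best with their own number among the arrays of other groups. The 3 mRNA probes of HFD+Abx vs CTR became 0 with quantile normalisation, equal medians, normexp with either normalisation, slide or array position as a block, slide 1 alone and adjustment with the circRNA probes, and 6 with a trended, robust variance, which gave 2 in HFD+Abx vs HFD, where array weights gave 1. Left-out arrays gave 0 to 4 and 0 to 2. At an unadjusted p with 1.5-fold, counts of 244, 609 and 843 became 19, 63 and 183 with normexp and 54, 146 and 300 with the authors' log2 table. They were 33, 93 and 231 among circRNAs brighter than every negative probe. That filter left 3242 circRNAs of the 13556, so these counts come from a smaller set and do not by themselves show a smaller share. Array position as a block gave 149, 546 and 243, and array weights gave 1003 for HFD+Abx vs HFD. Among the brighter circRNAs the correlation of the opposed changes was 0.064, with arrays left out it ranged from -0.41 to 0.0021, and with separate HFD arrays for the 2 comparisons it was 0.25, 0.11, 0.0092, 0.28, 0.091 and -0.12. ASCRP4002650, near background, went from -1.42 to 0.018 with normexp. ASCRP4013451 passed with the replicate block (-2.56, adjusted p = 0.014), against an adjusted p of 0.060 or more under its other alternatives. The cause was not tested elsewhere. Host gene and marker lists, and with them the estimated correlation, fry and single values per host gene, were not run. A signal of 3.88 to 4.60 times background limits what dim probes can show. The blocks by position, slide 1 alone, separate HFD arrays, the filter against negative probes and the joint adjustment were chosen after the data were seen.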

Other observations

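Other splits of the arrays, all but those of the F test counted after the real values had been seen, showed how often they give as many circRNAs. Each pair of groups has 10 splits, too few for a share under 0.05, and a real count of 0 is reached by every split, which tests nothing. For HFD vs CTR 10 splits gave at least the real 0 passing circRNAs (highest other 0), and 5 gave at least the real 489 of 13494 circRNAs with values on all arrays at an unadjusted p under 0.05 (highest other 1166). For HFD+Abx vs HFD the numbers were 10 (real 0, highest other 0) and 3 (real 1277, highest other 1826). For HFD+Abx vs CTR they were 10 (real 0, highest other 0) and 2 (real 1681, highest other 1760). For passing mRNA probes, 1 split reached the real 3 in HFD+Abx vs CTR (highest other 1), 10 reached the real 0 in HFD vs CTR (highest other 0) and 10 the real 0 in HFD+Abx vs HFD (highest other 2).

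For opposite changes chance was not excluded, since 34 of 100 groupings gave at least the real 132 at an unadjusted p under 0.05 (highest other 623). For the F test chance was not excluded either, since 24 of 100 gave at least the real 1199 at an unadjusted p under 0.05 (highest other 1978). Past the adjusted threshold both real counts were 0, which all 100 groupings reach by construction (highest other 0 and 107). The groupings with the most calls, 107, 82 and 78, all put CTR 1, CTR 3 and HFD 1 together, but a further grouping with these arrays together called 0. Counts this far above the real 0 may point to a structure of the samples, which was picked out after the counts were seen and was not tested. The grouping with 78 is the real one with CTR 2 and HFD 1 exchanged, and the 2 with more calls are not. CTR 1, CTR 3 and HFD 1 lie in the same position column of slide 1, which also holds CTR 2.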
